A study of Mus musculus with 6 samples.

How the data were processed

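Ear skin RNA from 3 C57BL/6 mice with DNFB-induced contact dermatitis was measured in 6 libraries, a DNFB-treated left ear and a solvent-treated right ear per animal. Per the labels' protocols, each animal was sensitised with 25 µL of 0.5% DNFB, and from day 6 the ears received 10 µL of 0.25% DNFB or of the solvent, 80% acetone and 20% olive oil, for 6 days. Per the same protocols, polyadenylated RNA was captured with oligo(dT) beads, libraries were amplified by PCR, and single-end reads of 50 bases were produced on a DNBSeq instrument. Per the submitters' processing notes the read aligner HISAT and the mouse build GRCm39 were used, with no version or further step given. The tool that assigned reads to genes, its annotation and its treatment of strand are not given in the sources used here, so overlapping and antisense genes may share counts. Copies in a near-identical family can share reads of this length, and values for such genes are given as uncertain.

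The authors deposited 1 table of 19309 genes with, per the file headers, read counts, FPKM and TPM for each library and a mean of each group. The deposited counts carry decimals, so they are estimated counts, and they were rounded here before testing. FPKM and TPM, per the file headers, are units scaled for gene length and library total, and were used only as a check: across genes, which are not independent replicates, the log2 ratio of group means with a pseudocount of 0.1 correlated with the fitted log2 fold change at r = 0.992 for TPM and 0.987 for FPKM. The deposited group means were compared with the means of the library columns and differed by rounding only. The table gives gene symbols with Entrez identifiers and no coordinates. The reference annotation at hand is of another build, so it was used for gene names only and no position is printed.

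Totals ranged from 19556800 to 20336900 estimated counts per library. A count of 0 in the 3 libraries of a group allows up to 3 counts, which was taken as the floor over the group. Intervals on count ratios are exact 95% intervals and cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Groups came from the titles of the samples, and the mouse numbers in those titles tie a DNFB ear to the vehicle ear of the same animal. The correlation of same-mouse deviations from the group means was −0.027, −0.148 and −0.046 for mice 1, 2 and 3, so libraries of 1 animal did not deviate together over all genes. This does not show that no set of genes did. The type I interferon list, for example, was highest within each group in the ears of mouse 3. Since the pairing comes from the animals, the fit with the mouse as a block was kept as an alternative.

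DNFB was compared with vehicle by edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr at its minimum count of 10 and the quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over the 15317 genes tested and a threshold of 0.05. The fit had no block. CPM are the counts scaled to a common library total by edgeR, with TMM factors, and the log2 fold changes are edgeR's, with an approximate standard error equal to the absolute log2 fold change divided by the square root of the F statistic. The 32 fixed lists of tissue, cell type and pathway genes were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2, at the preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. Counts of list members are given over all genes tested and adjusted over the list alone. The lists, the design, all alternatives but 1 and the rule for named genes were written before the data were examined. The rule took any matrix metalloproteinase, the 10 largest increases and 10 largest decreases among genes past the threshold with a mean log2 CPM of at least 2 and 1 direction in all 3 mice, and for each list up to 4 members past the threshold with the largest change and up to 2 of the most abundant that did not pass. Symbols of predicted or unnamed genes were left out of the largest changes. The text names part of that set, some of its genes are not reported here, and genes outside it are marked as chosen after their values were seen. Symbols were matched directly or through older names, with Rigi matched by hand to its older symbol Ddx58. Mmp21, Trac, Trbc1, Trbc2, Ighm, Igkc, Iglc1, Iglc2, Tpsab1, Cxcl11, Mx1, Mx2 and Krt85 are on the lists and were not analysed here.

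The alternatives were the mouse block, DESeq2 size factors, upper-quartile factors, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a test against a minimum fold of 1.5 (glmTreat), and leaving out each library or each mouse in turn. A test of the interferon list between DNFB ears alone, which argued against a weaker response throughout in mouse 3, was replaced by 1 within mice. The vehicle ear of that mouse was higher too. A fit of the DNFB library with mostly whole counts against the 3 vehicle libraries was chosen after seeing the data. So was the cutoff for the share of tissue markers away from their list median, an exact 95% interval wholly over 25%. An earlier cutoff, an interval wholly over 10%, was dropped after the shares were seen, and it would have argued against an even loss of muscle (10.3%) and sebaceous gland (12.8%) as well as of fat. The steps were tested on simulated data in which 98 genes changed 2-fold and 97 changed 4-fold among 15209 genes of the DNFB and vehicle libraries. There edgeR recovered 59.2% of the 2-fold and 89.7% of the 4-fold changes with 4 unchanged genes called, and DESeq2 80.6% and 93.8% with 42 unchanged genes called. Only a small part of the genes changed in the simulation, while 7862 of 15317 passed in the data, so these rates need not hold there. Nor can the simulation show how TMM scaling behaves when so many genes move. A list of genes raised 2-fold was recovered, with 0 of the other lists called. Each gene was simulated independently of the others, so this cannot show how the list test behaves where genes of a list vary together. In the data the estimated correlation reached 0.81, for the sterol list.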

Results

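RNA from whole ear skin was profiled in a mouse model of allergic contact dermatitis. C57BL/6 mice were sensitised on the first day with 25 µL of 0.5% DNFB (2,4-dinitrofluorobenzene, a hapten that binds skin proteins and provokes a T cell response). From day 6 the left ear of each animal received 10 µL of 0.25% DNFB and the right ear the solvent alone, and ears were taken after 6 days of this treatment. The series holds 6 libraries from 3 mice, 3 DNFB ears and 3 vehicle ears, so each treated ear has a vehicle ear of the same animal. Vehicle libraries 1, 2 and 3 held 20201400, 19556800 and 20087400 estimated counts (rounded), and DNFB libraries 1, 2 and 3 held 20336900, 20334600 and 20089900. The deposited table lists 19309 genes, of which 15317 had enough counts to be tested. The title of the series names MMP9, a gelatin-degrading protease, and the design asks which transcripts, among them the one for this enzyme, differ between the challenged and the solvent-treated ear.

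DNFB ears differed from vehicle ears across a large part of the measured transcriptome. By edgeR's quasi-likelihood test, 7862 of the 15317 genes passed an adjusted p of 0.05, 3966 higher and 3896 lower in DNFB ears, and 7834 of them moved the same way in all 3 mice. A change of more than 2-fold was seen in 3621 of these, 1995 higher and 1626 lower. Of the 10 expressed genes with the largest increases in all 3 mice, 6 had more than 3 counts in the vehicle group: Cxcl5, Il6, Acod1, Trem1, Cxcl3 and Cd300lf. Cxcl5, a chemokine that attracts neutrophils, went from 0.302 ± 0.141 to 437 ± 252 CPM (mean ± SD, n = 3 per group), a log2 fold change of 10.48 ± 0.78 (SE, adjusted p = 0.000148). The cytokine Il6 went from 0.214 ± 0.106 to 111 ± 61.3 CPM, and Acod1, the itaconate-producing enzyme of activated myeloid cells, from 0.363 ± 0.112 to 159 ± 40.6 CPM. Log2 fold changes were 8.67 for Trem1, 8.55 for Cxcl3 and 8.50 for Cd300lf, the last of these 9.11 without the vehicle ear of mouse 2. The other 4 had 3 counts or fewer in the vehicle group. Cstdc4 and Mrgpra2b had no count in the 3 vehicle libraries and were at least 368-fold and at least 183-fold higher in DNFB ears, against a floor of 3 counts over the group, and at least 240.5-fold and at least 119.9-fold higher without the vehicle ear of mouse 3. Both belong to families of near-identical genes whose 50-base reads can be shared, so the split between copies is uncertain. The granulocyte growth factor Csf3 gave a count ratio of 1156 (95% counting interval 319.8 to 9554), and the T cell cytokine Ifng one of 601 (95% counting interval 107 to 23761). All vehicle counts of both lay in the vehicle ear of mouse 3, and without it Csf3 was at least 504-fold and Ifng at least 131-fold higher. Without any other single library their ratios were 772 to 1586 and 401 to 623.

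The 10 expressed genes with the largest decreases in all 3 mice included Pck1, Krt77, Flg2 and Pvalb. Pck1, an enzyme of gluconeogenesis and glycerol synthesis, fell 13.1-fold, from 57.6 ± 24.3 to 4.39 ± 1.24 CPM (log2 fold change −3.71 ± 0.40, adjusted p = 0.000518). Krt77, a keratin of the upper epidermis, fell 9.70-fold, Flg2, a filaggrin family protein of the cornified layer, 8.66-fold, and Pvalb, a calcium buffer of fast muscle, 8.64-fold. The others were Cyp2e1 (−3.09 on the log2 scale), Nnat (−3.08), Inmt (−2.99), Mstn (−2.93), Tppp (−2.85) and S100a3 (−3.44, or −2.49 without the vehicle ear of mouse 2). The libraries separated by treatment: the correlation of log2 CPM across genes was 0.985 to 0.992 within vehicle ears, 0.962 to 0.987 within DNFB ears and 0.842 to 0.913 between groups. The first principal component, with 85.3% of the variance, parted the groups, with vehicle ears at −74.7, −73.8 and −64.9 and the DNFB ears of mice 1, 2 and 3 at 87.6, 81.3 and 44.6. The DNFB ear of mouse 3 thus lay nearer to the vehicle ears than the other DNFB ears did, with correlations of 0.903 to 0.913 to them against 0.842 to 0.868, and it also stood apart on the second component, with 6.59% of the variance. With 2 animals per group, 4487 genes passed without mouse 1, 2594 without mouse 2 and 9066 without mouse 3.

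Mmp9 (Entrez gene 17395) was 24.9-fold higher in DNFB ears. It measured 4.66 ± 1.18 CPM in vehicle ears and 116 ± 74.1 CPM in DNFB ears (mean ± SD, n = 3 per group), with a log2 fold change of 4.64 ± 0.64 (SE) and an adjusted p of 0.00127 by edgeR. The vehicle ears of mice 1, 2 and 3 stood at 4.80, 3.41 and 5.77 CPM and their DNFB ears at 172, 145 and 32.3 CPM, so the increase was seen in all 3 animals and was smallest in mouse 3. Without both libraries of mouse 3 the log2 fold change was 5.28.

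In the matrix metalloproteinase list, which includes Mmp9, 11 of 19 measured members rose, 2 fell and 6 did not pass (median log2 fold change 1.61, camera adjusted p = 0.00630, and adjusted p = 0.343 with an estimated correlation). The median was 2.24 over the members tested without the vehicle ear of mouse 3. Mmp8, the neutrophil collagenase, rose 81.7-fold to 54.7 ± 24.8 CPM and Mmp13, another interstitial collagenase, 45.5-fold to 33.5 ± 4.09 CPM. The stromelysin Mmp3 went from 42.1 ± 7.47 to 398 ± 136 CPM (log2 fold change 3.24 ± 0.28, adjusted p = 0.000231). Mmp19 rose by 2.65 ± 0.15 on the log2 scale, Mmp25 by 3.57 ± 0.36 and the membrane-bound collagenase Mmp14 by 1.61 ± 0.32. Single libraries weighed on 4 of the increases. Mmp10 and Mmp1b rose by 3.96 and 4.13 on the log2 scale but by 2.57 and 3.14 without the DNFB ear of mouse 3, and reads of Mmp1b can be shared with its neighbouring copy Mmp1a. The macrophage elastase Mmp12 rose by 3.58, and by 2.94 without the DNFB ear of mouse 2. Mmp23 (log2 fold change 0.61, adjusted p = 0.0343) no longer passed with the mouse as a block (adjusted p = 0.0525), with upper-quartile scaling (0.0531), by limma-voom (0.0521) or without any single library other than the DNFB ear of mouse 3 (adjusted p 0.0871 to 0.118). Mmp16 fell by 1.37 and Mmp28 by 0.88 on the log2 scale, the latter with an adjusted p of 0.0574 without the vehicle ear of mouse 3. Mmp2, the gelatinase related to Mmp9, was abundant in both groups, at 708 ± 53.4 CPM in vehicle ears and 759.5 ± 144 CPM in DNFB ears, and did not pass (log2 fold change 0.10 ± 0.16, adjusted p = 0.614). Mmp24 did not pass either (−0.23, adjusted p = 0.139).

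**Figure D1:**
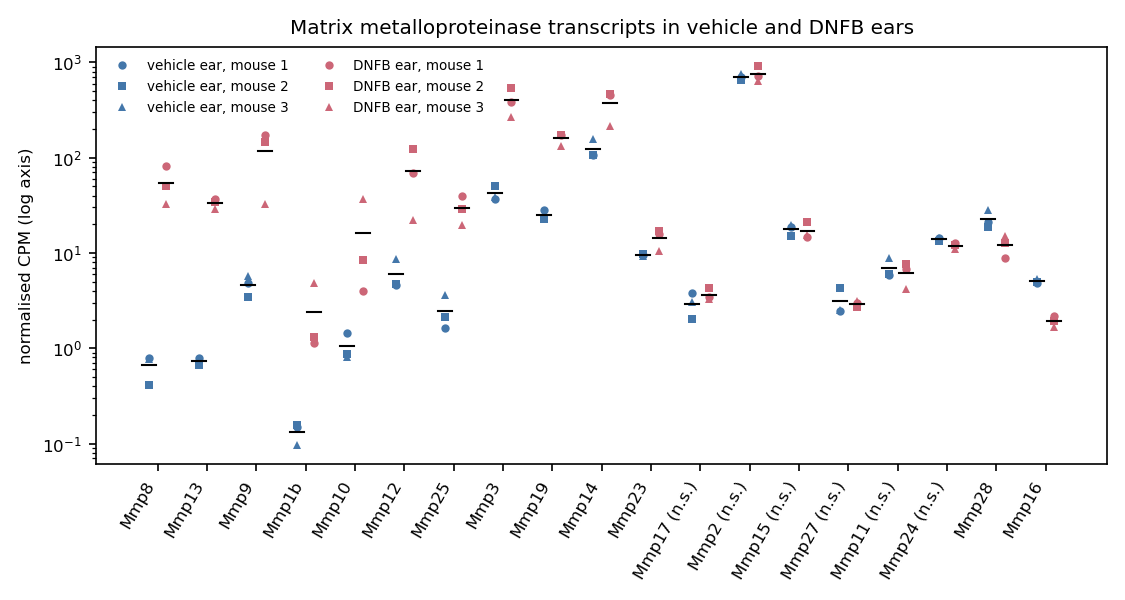
Normalised counts in CPM (log axis) of the 19 matrix metalloproteinase transcripts tested, ordered by log2 fold change, in vehicle ears (blue) and DNFB ears (red), with 1 symbol per mouse and a black bar at the mean of the 3 libraries; genes marked n.s. did not pass an adjusted p of 0.05. Mmp9 stands at 172, 145 and 32.3 CPM in the DNFB ears, all above the vehicle ears, and Mmp2 overlaps between the groups.

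The inhibitors of these proteases moved in opposite directions. Timp1 rose 38.4-fold, from 16.2 ± 1.14 to 622 ± 248 CPM (log2 fold change 5.26 ± 0.36, adjusted p = 0.000106), while Timp2, Timp3 and Timp4 fell by 0.72, 1.20 and 1.91 on the log2 scale. As a list of 4 genes the inhibitors had a median of −0.96 and a mean of 0.36, which differ in sign, and the list did not pass (camera direction down, adjusted p = 0.266, and 0.360 with an estimated correlation). Other proteases that act on the matrix, together with the plasminogen system, rose in 17 of 19 cases with none lower (median log2 fold change 1.46, camera adjusted p = 4.43e-07, and adjusted p = 0.301 with an estimated correlation). The aggrecanase Adamts4 rose 41.6-fold, the urokinase receptor Plaur 23.0-fold and Adam8 18.2-fold, and Ctsk did not pass (−0.17, adjusted p = 0.171). Fibrillar and interstitial matrix genes did not move as a list (median log2 fold change 0.08, camera adjusted p = 0.497, and adjusted p = 0.791 with an estimated correlation), with 6 higher, 2 lower and 13 of 21 not passing. Among them tenascin C, Tnc, went from 134 ± 16.9 to 1885 ± 1099 CPM, Col12a1 rose by 1.99 and Col3a1 by 1.02 on the log2 scale, and Bgn did not pass (−0.27, adjusted p = 0.131). The number of matrix genes past the threshold fell from 8 to 4 without the vehicle ear of mouse 1, to 5 without that of mouse 2 and to 4 without the DNFB ear of mouse 2. Adjusted over the list alone, 18 of the other proteases were higher, and the counts for metalloproteinases, inhibitors and matrix genes stayed as given.

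Leukocyte marker transcripts were higher in DNFB ears. Neutrophil markers showed the largest shift of the 32 lists, with 17 of 18 higher and none lower (median log2 fold change 5.68, camera adjusted p = 2.98e-09, and adjusted p = 0.280 with an estimated correlation). Trem1, an activating receptor of neutrophils and monocytes, went from 0.367 ± 0.0869 to 152 ± 86.7 CPM and Retnlg from 0.483 ± 0.165 to 74.3 ± 40.3 CPM, while Camp, a granule gene, stayed below 1 CPM in both group means and did not pass (0.75, adjusted p = 0.147). Monocyte and macrophage markers were higher in 19 of 20 cases (median log2 fold change 2.11, camera adjusted p = 2.98e-09, and adjusted p = 0.292 with an estimated correlation). Ly6c2, carried by inflammatory monocytes, rose 137-fold, the Fc receptor Fcgr1 39.2-fold and the endotoxin co-receptor Cd14 24.4-fold, and reads of Ly6c2 can be shared with Ly6c1. T cell markers followed with 15 of 17 higher (median log2 fold change 2.21, camera adjusted p = 1.23e-06, and adjusted p = 0.340 with an estimated correlation). Cd8a went from 0.512 ± 0.141 to 14.9 ± 7.99 CPM, Cd8b1 rose 26.8-fold and the costimulator Icos 21.9-fold, whereas Cd247 did not pass (log2 fold change 0.37, adjusted p = 0.133, or 0.0302 without the vehicle ear of mouse 3). The dendritic and Langerhans cell list had 15 of 19 members higher and 1 lower (median log2 fold change 1.65, camera adjusted p = 1.27e-05, and adjusted p = 0.274 with an estimated correlation), with the migration receptor Ccr7 up by 3.56 ± 0.52 and the costimulator Cd80 by 3.21 ± 0.29 on the log2 scale. The DNFB ear of mouse 3 differed from the mean of the other DNFB ears by a list median of −1.10 on the log2 scale for neutrophils, −0.69 for macrophages, −0.98 for T cells and −0.47 for dendritic cells.

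Markers of mast cells, basophils and eosinophils were higher in 9 of 13 cases and lower in 1 (median log2 fold change 0.58, camera adjusted p = 0.00169, and adjusted p = 0.274 with an estimated correlation). The basophil protease Mcpt8 went from 0.115 ± 0.0551 to 18.2 ± 10.5 CPM, the eosinophil lectin Siglecf from 0.232 ± 0.0727 to 5.78 ± 2.62 CPM, and the histamine-forming enzyme Hdc from 23.7 ± 8.50 to 364 ± 153 CPM, while the mast cell receptor Kit did not pass (0.17, adjusted p = 0.458, or 0.0496 without the DNFB ear of mouse 3). Only 4 B and plasma cell markers could be tested and the list did not pass (median log2 fold change 1.18, camera adjusted p = 0.205, and adjusted p = 0.343 with an estimated correlation). Of these Cd22 rose 15.1-fold and Cd79b 4.22-fold. Cd79b no longer passed without the vehicle ear of mouse 1 or 3 or the DNFB ear of mouse 1 or 2 (adjusted p 0.0535 to 0.0658), and the list itself passed without the DNFB ear of mouse 3 (adjusted p = 0.0243). Its median was 2.90 without that ear, 2.46 and 2.45 without the vehicle ear of mouse 1 or 2 and 2.00 without the DNFB ear of mouse 2, each over the members tested there. Adjusted over the list alone, the dendritic cell list had 16 members higher, the mast cell list 10 higher, and the neutrophil, macrophage, T cell and B cell lists the counts already given.

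The lists of type 1, type 2 and type 17 responses were each higher by the preset list test. All 18 genes of the type 1 and cytotoxic list were higher (median log2 fold change 4.40, camera adjusted p = 1.76e-10, and adjusted p = 0.104 with an estimated correlation). The granzymes Gzma and Gzmb each rose 131-fold, and the interferon-induced chemokine Cxcl10 went from 0.594 ± 0.242 to 100.2 ± 73.2 CPM (log2 fold change 7.38, or 6.61 without the DNFB ear of mouse 3). The type 2 list had 13 of 18 genes higher and 1 lower (median log2 fold change 1.74, camera adjusted p = 8.13e-05, and adjusted p = 0.104 with an estimated correlation). Il4 gave a count ratio of 96.6 (95% counting interval 32.7 to 471), Chil3, a chitinase-like protein of alternatively activated macrophages, rose 60.4-fold, and Arg1 rose by 4.94 on the log2 scale, or by 4.28 without the DNFB ear of mouse 1. The ratio of Il4 was 59.8 (20.0 to 294) without the DNFB ear of mouse 1, 193 (34.4 to 7664) without the vehicle ear of mouse 1 and 63.2 (21.4 to 308) without that of mouse 3. Ccl22 did not pass (0.24, adjusted p = 0.254). For the type 17 list 8 of 19 members were higher, 3 lower and 8 not past the threshold (median log2 fold change 0.69, camera adjusted p = 0.0473, and adjusted p = 0.323 with an estimated correlation). Il24 had a count ratio of 324 (95% counting interval 111 to 1576), Il19 rose 159.6-fold and the iron-binding protein Lcn2 14.9-fold. The ratio of Il24 was 209.7 (71.3 to 1021) without the DNFB ear of mouse 3, 649 (116 to 25672) without the vehicle ear of mouse 1 and 212 (72.4 to 1031) without that of mouse 3. The call of this list ended without the vehicle ear of mouse 3 (adjusted p = 0.0651), without the DNFB ear of mouse 3 (adjusted p = 0.269) and with 3 other choices (adjusted p = 0.0527 with DESeq2 size factors, 0.0823 with no filter on low counts and 0.155 with a stricter one).

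The type I interferon list rose in full, with 19 of 19 genes higher (median log2 fold change 3.69, camera adjusted p = 1.35e-10, and adjusted p = 0.274 with an estimated correlation). The nucleic acid sensor Zbp1 rose 47.4-fold, and the oligoadenylate synthetases Oas3 and Oas2 rose 34.8-fold and 32.7-fold. In the DNFB ear of mouse 3 the median of this list lay 0.51 above the other DNFB ears on the log2 scale. The vehicle ear of that mouse was higher too. The mean log2 CPM of the list rose by 3.32, 3.28 and 3.38 within mice 1, 2 and 3. Chemokine ligands were higher in 23 of 32 cases and lower in 3 (median log2 fold change 2.76, camera adjusted p = 2.63e-07, and adjusted p = 0.104 with an estimated correlation), with Cxcl2 at 1.19 ± 0.500 and 293 ± 188 CPM and Ccl4 at 0.235 ± 0.112 and 83.2 ± 40.2 CPM in vehicle and DNFB ears. Genes of interleukin 1 signalling and innate inflammation were higher in 19 of 21 cases and lower in 1 (median log2 fold change 1.88, camera adjusted p = 5.89e-08, and adjusted p = 0.274 with an estimated correlation). Il1b went from 3.71 ± 1.73 to 801 ± 350.2 CPM and Osm, a cytokine of activated myeloid and T cells, rose 144-fold, but Il1a, stored in keratinocytes, did not pass (−0.49 ± 0.33, adjusted p = 0.243, or 0.0194 without the DNFB ear of mouse 3). Among itch mediators and receptors 16 of 21 were higher and none lower (median log2 fold change 1.70, camera adjusted p = 1.20e-05, and adjusted p = 0.104 with an estimated correlation). Nppb, a peptide known from itch-sensing neurons, rose 37.1-fold in whole ear skin, and the cells that made it were not identified. Il13 rose 18.9-fold, while the protease receptor F2rl1 did not pass (0.20, adjusted p = 0.307). Adjusted over the list alone, the counts of the 7 cytokine, interferon, chemokine and itch lists were the same.

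Keratinocyte lists moved in opposite directions. Of 30 epidermal differentiation and barrier genes, 23 fell and none rose (median log2 fold change −1.56, camera adjusted p = 9.24e-07, and adjusted p = 0.358 with an estimated correlation). Hornerin, Hrnr, went from 2826 ± 640.0 to 566 ± 230.1 CPM, and Lce1m fell by 2.78 on the log2 scale, or by 3.53 without the DNFB ear of mouse 3. The protease Klk7 did not pass (−0.64, adjusted p = 0.123, or 0.000700 without that ear). This list stood 1.01 higher in the DNFB ear of mouse 3 than in the other DNFB ears. The stressed keratinocyte list went the other way, with 22 of 25 members higher and 1 lower (median log2 fold change 2.39, camera adjusted p = 2.98e-09, and adjusted p = 0.274 with an estimated correlation). The wound keratins Krt6b and Krt16 rose from 33.7 ± 22.2 to 1864 ± 297 CPM and from 67.5 ± 21.7 to 1443 ± 311 CPM. Sprr2a1, a cornified-envelope precursor, rose 42.1-fold, its log2 fold change moving from 5.39 to 6.08 without the vehicle ear of mouse 1, and the growth factor Areg rose 23.8-fold. Sprr2b did not pass (0.67, adjusted p = 0.0645). Members of the Sprr2, Lce and Krt6 families resemble each other closely, so their separate values are uncertain. Cell cycle genes were higher in 23 of 24 cases (median log2 fold change 1.17, camera adjusted p = 2.98e-09, and adjusted p = 0.280 with an estimated correlation), with Ccne1 up 3.97-fold and Plk1 3.57-fold. Endothelial adhesion and angiogenesis genes were higher in 12 of 16 cases and lower in 1 (median log2 fold change 1.01, camera adjusted p = 0.000570, and adjusted p = 0.343 with an estimated correlation). The leukocyte adhesion molecules Selp, Vcam1 and Icam1 rose 18.0-fold, 7.58-fold and 5.74-fold, and Kdr did not pass (0.58, adjusted p = 0.0540, or 0.0108 without the vehicle ear of mouse 3 and 0.0351 without its DNFB ear). Adjusted over the list alone, 23 stressed keratinocyte and 13 endothelial genes were higher, and the differentiation and cell cycle counts stayed as given.

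Markers of other tissues held in an ear were lower in DNFB ears. All 17 skeletal muscle genes fell (median log2 fold change −1.21, camera adjusted p = 1.03e-05, and adjusted p = 0.343 with an estimated correlation), among them the fast myosin Myh4, from 292 ± 92.7 to 44.5 ± 20.0 CPM, and Actn3, 6.05-fold. All 12 adipocyte genes fell too (median log2 fold change −1.58, camera adjusted p = 9.44e-07, and adjusted p = 0.104 with an estimated correlation), with the lipid droplet protein Cidec down 4.27-fold and leptin, Lep, 6.39-fold. Cartilage markers fell in 13 of 14 cases (median log2 fold change −1.31, camera adjusted p = 1.83e-05, and adjusted p = 0.292 with an estimated correlation), with Col9a1 down 3.63-fold and Cnmd 3.03-fold. Sebaceous gland markers fell in 11 of 14 (median log2 fold change −1.36, camera adjusted p = 8.13e-05, and adjusted p = 0.343 with an estimated correlation). The desaturase Scd1 went from 7470.4 ± 161 to 1836 ± 633 CPM and the melanocortin receptor Mc5r fell 4.53-fold, while Soat1 did not pass (−0.20, adjusted p = 0.231). The DNFB ear of mouse 3 differed from the mean of the other DNFB ears by a list median of 1.00 on the log2 scale for sebaceous gland markers, 1.30 for melanocyte, 0.71 for Schwann cell, 0.58 for cartilage, 0.35 for muscle and −0.10 for adipocyte markers. Of the adipocyte markers 7 of 12 were lower there. Schwann cell markers fell in 6 of 10 cases (median log2 fold change −1.07, camera adjusted p = 0.00859, and adjusted p = 0.360 with an estimated correlation), S100b by 1.89 and Mbp by 1.13 on the log2 scale. For melanocyte markers 2 of 8 were lower (median log2 fold change −0.90, camera adjusted p = 0.0351, and adjusted p = 0.360 with an estimated correlation). These were Oca2 (−1.67, adjusted p = 0.0324) and Mlana (−1.15, adjusted p = 0.0386), and neither passed without any single library other than the DNFB ear of mouse 3 (adjusted p 0.0645 to 0.111 for Oca2 and 0.0665 to 0.121 for Mlana). Without that ear they stood at −2.65 and −1.74, 6 members passed and the median of the list was −1.49. The call of the list ended without the vehicle ear of mouse 2 or 3 (adjusted p = 0.0530 and 0.0518). Dct did not pass (−0.87, adjusted p = 0.0851), and did with the mouse as a block (adjusted p = 0.0337) or without the DNFB ear of mouse 3 (0.000512). Adjusted over the list alone, 7 Schwann cell and 0 melanocyte genes were lower, and the other 4 counts stayed as given.

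Hair follicle markers did not pass as a list (median log2 fold change −1.67, camera adjusted p = 0.0683, and adjusted p = 0.360 with an estimated correlation), with 5 of 10 lower, or 7 adjusted over the list alone. The mean log2 CPM of the list changed by −2.31, −2.33 and 0.71 within mice 1, 2 and 3, so in mouse 3 it was higher in the DNFB ear. In vehicle ears the inner root sheath keratin Krt71 stood at 31.3 and 51.9 CPM in mice 1 and 2 but at 0.192 CPM in mouse 3, against 2.77 ± 0.187 CPM in DNFB ears, and it did not pass (adjusted p = 0.0585, or 0.000728 without the vehicle ear of mouse 3). Krt28 passed in the full set (log2 fold change −2.19, adjusted p = 0.0378) and not without any single vehicle ear or the DNFB ear of mouse 2 (adjusted p 0.0638 to 0.132), and stood at −3.46 without the DNFB ear of mouse 3. The list passed with the mouse as a block (adjusted p = 0.0175) and without the vehicle ear of mouse 3 (1.34e-05), the DNFB ear of mouse 2 (0.0469) or that of mouse 3 (0.0303). The number of its members past the threshold went from 5 to 0 without the DNFB ear of mouse 2 to 1 without the vehicle ear of mouse 2, to 3 without that of mouse 1 and to 8 without that of mouse 3. The median was −3.03 without the DNFB ear of mouse 3, −2.84 without the vehicle ear of mouse 3 and −2.34 without the DNFB ear of mouse 2, each over the members tested there.

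Sterol biosynthesis genes fell in 17 of 18 cases (median log2 fold change −0.88, camera adjusted p = 0.000127, and adjusted p = 0.360 with an estimated correlation). Msmo1 went from 672 ± 72.4 to 242 ± 113 CPM. All 18 genes were higher in the DNFB ear of mouse 3 than in the other DNFB ears (median difference 0.65 on the log2 scale). The mean log2 CPM of the list lay at −1.30, −0.97 and −0.46 from the vehicle ears in the DNFB ears of mice 1, 2 and 3, and that of the sebaceous gland list at −1.93, −1.46 and −0.84. The count of sterol genes past the threshold was 8 without the vehicle ear of mouse 1, and 9 without the vehicle or the DNFB ear of mouse 2. Circadian clock genes were lower in 9 of 14 cases (median log2 fold change −0.89, camera adjusted p = 8.91e-05, and adjusted p = 0.274 with an estimated correlation), or 10 adjusted over the list alone. The clock output factor Hlf fell 3.20-fold, Cry2 2.53-fold and Per3 2.25-fold. Immediate early genes, which also respond to dissection, were higher in 10 of 13 cases and lower in 1 (median log2 fold change 1.45, camera adjusted p = 0.00116, and adjusted p = 0.274 with an estimated correlation). Junb rose 5.20-fold and Atf3 4.90-fold. Fos was already high in the vehicle ear of mouse 3, at 113 CPM against 19.1 and 18.2 CPM, and its call (adjusted p = 0.0454) ended without any single library other than the vehicle or DNFB ear of mouse 3 (adjusted p 0.0947 to 0.126), while its log2 fold change went from 2.16 to 3.60 without that vehicle ear. Red blood cell transcripts did not pass (median log2 fold change −0.55, camera adjusted p = 0.239, and adjusted p = 0.596 with an estimated correlation), though the list did without the DNFB ear of mouse 1 (adjusted p = 0.0458, with 3 members passing in place of 0). Hba-a1 and Hbb-bs had log2 fold changes of −1.12 and −0.55 with adjusted p of 0.0880 and 0.161, against 0.00827 and 0.0259 with the mouse as a block and 0.00483 and 0.0270 without the DNFB ear of mouse 1. Each has a near-identical copy. Adjusted over the list alone, the sterol, immediate early and red blood cell counts were the same.

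**Figure D2:**
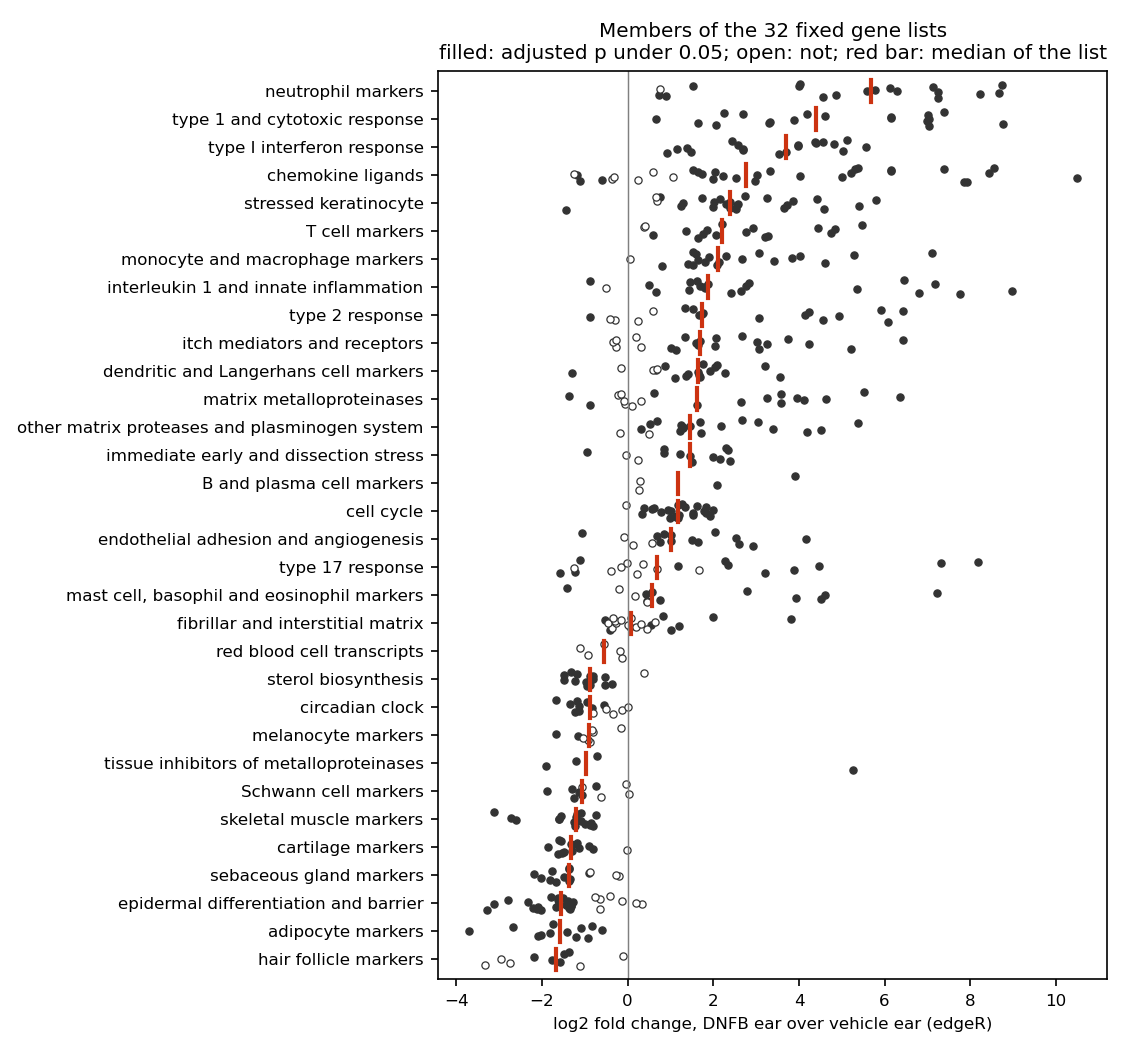
Log2 fold change (DNFB over vehicle, edgeR, n = 3 per group) of each tested member of the 32 gene lists, 1 row per list ordered by median, with filled points for genes past an adjusted p of 0.05, open points for the others and a red bar at the median. Neutrophil markers have the highest median, 5.68, and hair follicle markers the lowest, −1.67.

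By camera with a preset correlation of 0.01 between genes, 27 of the 32 lists passed, 18 up and 9 down. With the correlation estimated from the 6 libraries 0 passed and the lowest adjusted p was 0.104, while fry, which asks only whether the genes of a list move one way on balance, passed 27, 19 up and 8 down. The preset test also passed 14 to 25 lists in the other 9 splits of the 6 libraries into 3 and 3. Those splits mix DNFB and vehicle ears in both groups and are not free of the treatment difference.

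**Figure D3:**
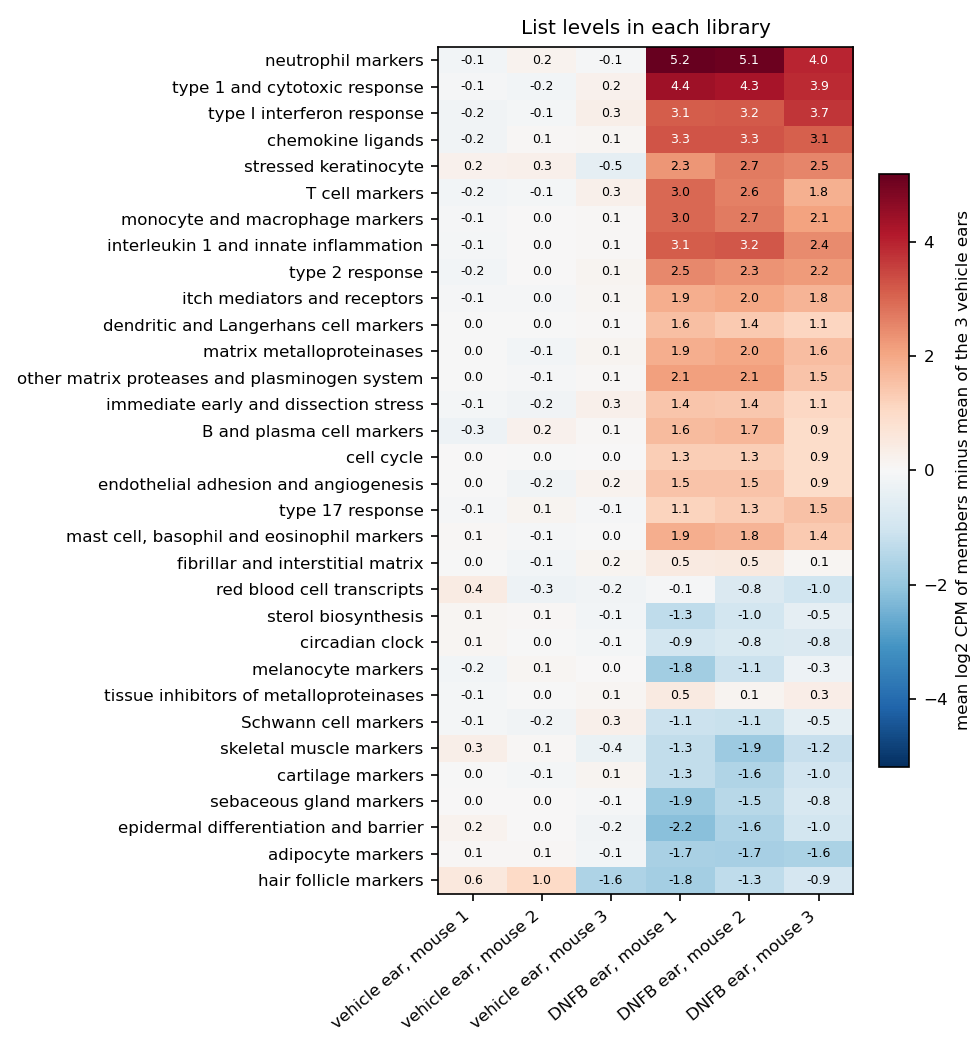
Mean log2 CPM of the members of each of the 32 gene lists in each of the 6 libraries, minus the mean of the 3 vehicle ears, with the value printed in each cell and red for higher and blue for lower. In the DNFB ear of mouse 3 the leukocyte lists lie below and the type I interferon list above the other DNFB ears. In the vehicle ear of that mouse the interferon list lies above the other vehicle ears.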

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

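The number of genes past the threshold moved by over 1.5 times under 3 alternatives. With a minimum fold of 1.5 it was 3401, with 1993 genes higher in DNFB ears and 1408 genes lower in DNFB ears, since that test asks for a larger change. Without mouse 1 it was 4487 (2481 higher and 2006 lower) and without mouse 2 it was 2594 (1658 higher and 936 lower). Fewer samples alone do not account for this, since 9066 passed without mouse 3, and the cause was not tested. Over all fits that left out a library or a mouse, the number ranged from 2594 to 9108, with 1658 to 4585 higher and 936 to 4601 lower; the most passed without the DNFB ear of mouse 3. DESeq2 gave 8058, limma-voom 7839, DESeq2 size factors 7859, upper-quartile scaling 7943, no filter on low counts 7760 and the stricter filter 7655. Upper-quartile scaling moved the median log2 fold change by −0.074 and the share of calls that were higher from 50.4% to 43.8%. None of the 7862 genes that an alternative tested took the opposite direction there. Mmp9 passed under each alternative in which single genes were followed, with log2 fold changes of 4.25 to 5.28. With the minimum fold of 1.5 single genes were not followed. Mmp2, which did not pass, ranged from −0.11 to 0.28 when a library or mouse was left out, and was negative without the DNFB ear of mouse 2 (−0.05) and without mouse 2 (−0.11); the cause was not tested.

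With the mouse as a block 6601 genes passed, 6459 of them among the 7862 and in the same direction. The block changed the calls of Mmp23, Dct, Hba-a1, Hbb-bs, Mcpt4 (adjusted p = 0.0555) and the hair follicle list, and of no other list or gene followed through the alternatives. Sparc and Dcn, named further on, were not among the genes followed. By DESeq2, Kdr, Krt71, Dct and Hba-a1 passed (adjusted p = 0.0306, 0.0486, 0.0380 and 0.0287), as did Kdr and Dct by limma-voom (0.0439 and 0.0423), and Fos did not pass with upper-quartile scaling (0.0510). Of 2209 values of named genes under alternatives, 2105 kept their direction and side of the threshold, 72 were no longer past it, 30 came to pass it and 2, both of Mmp2, changed sign. The number of lists called was 0 with an estimated correlation and 26 to 28 under the other alternatives in which lists were tested. Lists were not tested by DESeq2, limma-voom or with the minimum fold of 1.5. By fry the melanocyte list did not pass (adjusted p = 0.0599) and the B cell list did (0.0155). With no filter on low counts the B cell and hair follicle lists passed (0.0308 and 0.0232). In a fit chosen after seeing the data, DNFB library 1 against the vehicle libraries, 7419 genes passed, and the lone sample is assumed there to vary like the vehicle group. Depth limits genes with 3 or fewer vehicle counts to a bound or a counting interval in place of a fold change.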

Other observations

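Every gene, family and test in this part, apart from the splits of the libraries, was chosen after the results were seen. Fgf23, a hormone known from bone that lowers blood phosphate, rose nearly as much as the 10 largest increases, at 0.366 ± 0.116 CPM in vehicle ears and 130.0 ± 20.3 CPM in DNFB ears (mean ± SD, n = 3 per group, log2 fold change 8.45 ± 0.23, edgeR adjusted p = 9.35e-06, higher in 3 of 3 mice). Mast cell genes did not move as 1 group: the receptor Mrgprb2 fell by 1.41 on the log2 scale (adjusted p = 0.00272) while the granule proteases Cma1, Cpa3 and Mcpt4 rose by 0.75, 0.58 and 0.44 (adjusted p = 0.00103, 0.00435 and 0.0121, the last 0.0555 with the mouse as a block). Cd207, which encodes langerin of Langerhans cells, fell by 1.30 (adjusted p = 0.0420), but leaving out any single library other than the DNFB ear of mouse 3 ended that call (adjusted p 0.0785 to 0.125), and without that ear it fell by 2.06.

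Genes were also grouped by the letters of their symbols into 280 families of at least 8 tested members, and each was compared with all other genes by Fisher's exact test with Benjamini-Hochberg adjustment. An excess of higher members was found in 24 families and an excess of lower members in 7, and since members of a family are regulated together these p-values are too small. The interferon-induced GTPases of the Gbp family were higher in 10 of 10 cases (median log2 fold change 3.41, adjusted p = 5.11e-05), the Ifi family in 15 of 16 (2.61, adjusted p = 1.48e-06), the Slfn family in 7 of 8 (3.15, adjusted p = 0.00881) and the lymphocyte GTPases of the Gimap family in 8 of 8 (1.55, adjusted p = 0.000501). Skint genes, named for the selection of epidermal T cells, were lower in 10 of 11 cases (median −1.71) and the esterases of the Aadacl family in 9 of 9 (median −1.85), each with adjusted p = 0.00134. Claudins, the sealing proteins of tight junctions, were lower in 11 of 15 cases and higher in 1 (median −1.28, or −1.87 without the DNFB ear of mouse 3, adjusted p = 0.00834), and the Wnt receptors of the Fzd family lower in 8 of 10 (median −0.80, adjusted p = 0.0177). Within the late cornified envelope family all 14 Lce1 genes were lower (median −2.08, or −2.84 without the DNFB ear of mouse 3) and all 6 Lce3 genes higher (median 2.43), though their reads can be shared. No family named here changed direction with DESeq2 size factors or upper-quartile scaling, which left 7 of 8 Gimap genes past the threshold.

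For each of 4 counts, only 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many results, and so few splits cannot give a share under 0.05. By edgeR the real split gave 7862 genes, with 8863 at an unadjusted p under 0.05. The highest of the others was 0, and 16 to 554 genes had an unadjusted p under 0.05 there. Each of the other splits put DNFB and vehicle ears together in both groups, so the treatment difference widened the spread within groups. Few or no calls were thus built in, and the 0 does not measure how many genes pass without a treatment difference. Their groups still differed in the share of DNFB ears, so lists called there are no such measure either. Genes higher numbered 3966 and genes lower 3896, and the highest of the others was 0 for both. Lists called at the preset correlation numbered 27 in the real split and up to 25 in another, so their number barely set the real split apart. By fry the numbers were 27 and at most 1, and with an estimated correlation 0 and 0. DESeq2 and limma-voom were not run on the other splits. The real split parts the ears of all 3 mice, as do 3 of the others, which called 25, 23 and 14 lists and 0 genes.

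The first pattern lies in the counting. Among genes with more than 1000 estimated counts, values within 0.005 of a whole number made up 14.7% in DNFB library 2 and 11.5% in DNFB library 3, and 66.1% to 67.3% in the other 4 libraries. If this difference had produced the DNFB calls, they would not extend to mouse 1, whose 2 libraries were alike, but of 4463 genes called from mice 2 and 3 alone and tested in mouse 1, 4439 went the same way there (99.5%), which argues against it. It also did not follow DNFB treatment, since DNFB library 1 stood at 66.1%. The source of the difference stays open, and no biological explanation was tested.

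The next pattern is the lower Mmp9 in the DNFB ear of mouse 3, with a log2 difference of −2.28 from the mean of the other DNFB ears. The depth of that library was 0.988 of the mean of the others, which argues against lower depth as the cause. Of the 27 lists called, 24 changed less between the ears of mouse 3 than in both other mice and 3 more. The change in mouse 3 was set against the mean of the others, with a 95% prediction interval from the other mice. That interval left out 0 for 5 of the 27, each a smaller change in mouse 3. The lists that changed more were type I interferon (difference 0.0800, interval −0.40 to 0.56), type 17 (0.40, −0.26 to 1.06) and stressed keratinocyte (0.75, −3.42 to 4.91). Most lists thus changed less in mouse 3. The interval rests on a single value from each of the other mice, so its width follows how closely these happened to agree. It left out 0 for the mast cell, basophil and eosinophil list (difference −0.45, interval −0.51 to −0.38). For T cell markers, which differed by more, it did not (−1.38, −6.12 to 3.35). The number of lists beyond it is thus no measure of the response in mouse 3, and whether the response was weaker throughout stays open. Fewer neutrophils may account for the lower Mmp9, since all 18 neutrophil markers were lower there than in the other DNFB ears (median −1.10). But Mmp9 lay just beyond the lowest of them (−2.26), and the neutrophil collagenase Mmp8 differed by only −0.98. Within mice the mean of the neutrophil list differed by −1.09 in mouse 3 (95% prediction interval −6.08 to 3.90), which leaves fewer neutrophils unsettled. Macrophage and T cell markers were lower too, so the part of neutrophils, of other cells and of a weaker response in this ear cannot be told apart.

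The third pattern is the lower level of muscle, fat, cartilage and sebaceous gland markers in DNFB ears, 53 of 57 genes. Dilution of all resident tissue by added cells would lower fibrillar matrix genes by a like amount if DNFB left their transcription unchanged. Their median log2 fold change was 0.0772 (95% bootstrap interval −0.27 to 0.56, too narrow as members vary together). Their mean changed by 0.50, 0.65 and −0.05 within mice 1, 2 and 3, where each of the 4 lists fell by at least 0.78. This argues against dilution as the whole cause only under that condition, which was not tested. Of the 21 matrix genes 6 rose, among them Tnc by 3.82 and Col12a1 by 1.99, and 2 fell, Sparc (−0.53) and Dcn (−0.42). Higher transcription of matrix genes could thus mask a dilution, which stays open. A smaller share of a tissue in the piece taken would move all genes of its list by 1 amount if no other tissue expressed them. Of the fat markers 75.0%, 9 of 12, lay more than 2 SE from their own median (exact 95% interval 42.8% to 94.5%). The interval takes genes as independent, which they are not. The log2 fold changes of fat markers ran from −3.71 to −0.60. This argues against an even loss of fat as the whole cause, though expression of these genes in other cells of the ear was not measured. The share was 29.4% for muscle (interval 10.3% to 56.0%), 21.4% for cartilage (4.66% to 50.8%) and 35.7% for sebaceous gland markers (12.8% to 64.9%), and these few genes leave a smaller share of those 3 tissues open. The share also depends on the standard errors, mostly larger for muscle than for fat genes, while muscle log2 fold changes ran from −3.11 to −0.73. A lower share of markers past 2 SE is thus no sign of a more even loss. An uneven loss and lower transcription under DNFB also stay open and were not tested.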
